A study of Mus musculus with 8 samples.

How the data were processed

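RNA was measured by sequencing in whole liver of mice kept on a high fat diet. The labels give 8 samples, of which 5 are CTRL and 3 are OPA1_LKO, the livers in which Opa1 was deleted in hepatocytes. Per the labels' protocols, total RNA was taken up with a column kit and made into stranded, poly(A)-selected libraries. The labels do not say which exons of Opa1 were removed, whether each sample is a separate animal, what sex the mice were, or whether the libraries were made in batches. All p-values therefore measure the spread between these samples, which may be technical in part, and no batch could be examined.

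The submitters' processing notes name STAR, RSEM, StringTie and MultiQC, without versions, and the mouse genome build mm10. The gene annotation release and the order of these tools are not given in the sources used here. The authors deposited 4 tables, each with 1 column for each library. The values of 2 of them are expected counts as estimated by RSEM, per gene and per transcript, and the deposited expected counts are not normalised. The other 2 deposited tables hold TPM, the transcript abundance corrected for length, again per gene and per transcript, which RSEM scales to the same sum in each library. RSEM divides a read that matches several places among them by estimation, so levels of near-identical genes (the Sult2a, Cyp2c, Cyp3a, Mup, Saa, Orm and Serpina1 families here) are uncertain in how reads were split between members. No row lacked a gene name, no symbol occurred more than once, and no column of another sample was present.

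Gene expected counts were rounded to whole numbers. Library totals ranged from 16076404 to 20471271, and the 8 libraries held a count for between 17336 and 19437 of the 35976 genes. Genes with low counts were removed with the default rule of filterByExpr (a count minimum of 10 in a typical library and 15 in total), which left 14036 genes. These were scaled with trimmed mean of M-values (TMM) factors, and OPA1_LKO was compared with CTRL by the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term. The p-values were adjusted by the Benjamini-Hochberg method over the 14036 genes, and an adjusted p under 0.05 was called changed. Standard errors (SE) of log2 fold changes were derived from the fold change and the test statistic. Levels are given as CPM, counts scaled to a fixed total by the TMM-scaled library sizes, as mean ± SD over libraries.

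The 48 gene lists (884 entries) were written from general knowledge of liver biology before the data were examined, none of them from the study, as were the main test, its alternatives and the rule for named genes. Of the entries, 880 matched a gene of the table, 17 of them through another symbol in a RefSeq gene table of assembly GRCm38.p6. The 46 lists with at least 5 tested genes were compared with all other tested genes by camera of limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and adjusted by Benjamini-Hochberg over the lists. The correlation estimated from these libraries for each list, and fry, which asks whether the genes of a list move one way without reference to other genes, were run beside it. Counts of changed members are given over all genes tested and, where so stated, adjusted over the list alone.

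Named genes were fixed by rule. The rule took Opa1, the 12 genes with the largest rise and the 12 with the largest fall among changed genes with a mean of at least 1 CPM, a full separation of the groups and a symbol that is not a provisional or pseudogene name, the 4 members of each list with the smallest p, all tested members of the lists for bile acid synthesis, conjugation and transport and for mitochondrial fusion, fission and cristae, and the 10 most abundant genes. Some genes that the rule names are not reported here, fewer than the rule allows are named, and members not named are summarised by their counts. Fgf21, Apcs, Xist, Ddx3y, Eif2s3y, Kdm5d, Uty, Krt19, Epcam, Cldn7, Cftr, Apoc1 and Apoc4 fall outside the rule and were chosen after their values were seen. For each Opa1 transcript with a mean of at least 0.1 TPM, the TPM and its share of the Opa1 total were compared by an exact two-sided permutation test over the 56 ways to divide the libraries into 5 and 3, of which the smallest p is 0.0357.

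The procedure was tested on simulated counts with the means, library sizes and dispersions of the real libraries, with 200 of 14036 genes changed. It recovered 10% of the 50 genes changed by 1.5-fold, 38% of those changed by 2-fold, 84% of those changed by 4-fold and 96% of those changed by 8-fold, and 3 of the 13836 unchanged genes were called. A list shifted by 1.5-fold was called and 0 other lists were. The simulation drew each gene independently, whereas the correlation between genes estimated in the real lists reached 0.926. It therefore cannot show how the list test behaves when genes are correlated. For a gene with no count in CTRL the fold is a lower bound against a floor of 3 counts over the group. A gene with 1 to 3 counts in CTRL is given as the ratio to those counts with an exact 95% Poisson interval, and floors and intervals cover counting error only.

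Alternatives were DESeq2 1.42.0, its size factors or upper-quartile factors in edgeR, other filters on low counts, limma-voom with a quality weight for each library, limma on log2(TPM + 1) or log2(TPM + 0.1), the removal of the most abundant and mitochondrially encoded genes before scaling, 1 surrogate variable from sva 3.50.0, a block for the replicate number, a test against a fold of 1.5, and each library left out in turn. Replicate numbers 4 and 5 occur only in CTRL. The block therefore takes up these libraries, and its group effect rests on replicates 1 to 3 of each group. Fits without the CTRL replicates 1 and 3 together were added after the data were seen.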

Results

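Liver RNA was compared between 5 control samples (CTRL) and 3 samples from mice with a hepatocyte deletion of Opa1 (OPA1_LKO), all on a high fat diet. Opa1 encodes the dynamin-related GTPase that fuses the inner mitochondrial membrane, and the question named by the study is how the loss of this fusion in hepatocytes acts on fatty liver, metabolism and bile acid conjugation. The libraries held between 16076404 and 20471271 estimated reads on genes. Transcripts of the mitochondrial genome took 11.96% to 26.4% of these, with the highest share in CTRL replicate 3. The first principal component of log2 CPM carried 45.4% of the variance and placed the OPA1_LKO libraries between -50.5 and -36.7 and the CTRL libraries between -13.4 and 57.7. CTRL replicate 1 stood apart on the second component, at -58.4. In this library Apoe, the apolipoprotein of remnant particles, was at 134 CPM, against 20760 to 33180 CPM in the other 7 libraries. Because of this, counts of changed genes are also given without it.

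Opa1 itself lies on chromosome 16 from 29579281 to 29663127 (GRCm38.p6). Its level was 48.1 ± 6.90 CPM in CTRL (SD, n = 5) and 31.0 ± 5.53 CPM in OPA1_LKO (SD, n = 3). The estimated counts were 751, 923, 787, 840 and 819 in the CTRL libraries and 534, 765 and 575 in the OPA1_LKO libraries. The log2 fold change was -0.63 ± 0.17 (SE), with an adjusted p of 0.0539 by the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment, just outside the threshold. In CPM all 3 OPA1_LKO libraries were below all 5 CTRL libraries. Without CTRL replicate 1 the adjusted p by the same edgeR test and Benjamini-Hochberg adjustment was 0.0272, and with DESeq2 it was 0.00917. The edgeR p with Benjamini-Hochberg adjustment was between 0.0726 and 0.236 without any one of the other libraries, highest without OPA1_LKO replicate 1, and the limma p was 0.166 on the log2(TPM + 1) scale. Reads from exons outside the deleted part, and from liver cells other than hepatocytes, are counted in these values. Of the 3 Opa1 transcripts above 0.1 TPM, NM_133752.3 was at 6.03 ± 0.615 TPM in CTRL and 4.93 ± 0.655 TPM in OPA1_LKO, and XM_006522656.3 at 2.21 ± 1.05 and 0.537 ± 0.573 TPM. The share of XM_006522656.3 in the Opa1 total was 23.0% ± 8.09 in CTRL and 8.16% ± 7.71 in OPA1_LKO. None of the 6 transcript comparisons passed the exact permutation test, whose lowest p among them was 0.0714.

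As sets tested by camera with a preset correlation, genes of the amino acid stress response, female-biased liver genes and duct and matrix genes were higher in OPA1_LKO, and genes of lipid uptake and droplets and of the acute phase were lower. The adjusted p of these 6 lists was between 0.334 and 0.735 with an estimated correlation, with which 0 of 46 lists were called. Asns, which makes asparagine, was at 0.968 ± 0.896 CPM in CTRL and 24.2 ± 12.3 CPM in OPA1_LKO. Cidea, a lipid droplet protein of fatty liver, went the other way, from 14.9 ± 7.83 to 0.514 ± 0.298 CPM. Scd1, the desaturase that makes monounsaturated fatty acids, was at 5252 ± 1891 CPM in CTRL and 804 ± 299 CPM in OPA1_LKO. In all, 846 of 14036 genes changed, 469 of them higher and 377 lower in OPA1_LKO, of which 351 and 151 changed by at least 2-fold. Without CTRL replicate 1 the count was 1701 genes, 924 higher and 777 lower. It was 2919 without CTRL replicates 1 and 3 together, a pair chosen after the data were seen. These CTRL libraries lay nearest to OPA1_LKO on the first principal component, at -13.4 and 9.38. Leaving out the controls nearest to OPA1_LKO can raise the count by itself, so these higher counts add no support.

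Among the largest rises, Vmn2r3, a pheromone receptor gene, reached 43.1 ± 34.2 CPM from 0.0881 ± 0.161 CPM in CTRL. Mmp7, a matrix protease made by injured epithelium, rose from 0.0651 ± 0.0871 to 11.2 ± 3.51 CPM, and H19, an imprinted RNA of fetal liver, from 0.350 ± 0.217 to 22.03 ± 12.98 CPM. Areg, a ligand of the epidermal growth factor receptor, rose by 5.21 ± 0.67 on the log2 scale (SE). Msmp, Wfdc3 and Tenm2 rose by 6.72 ± 0.43, 6.84 ± 0.61 and 5.36 ± 0.98, though Wfdc3 and Tenm2 each had a CTRL replicate 1 above the other CTRL libraries. Gldn had 3 counts over the 5 CTRL libraries and 691 over the OPA1_LKO libraries, a ratio of 327.9 with a 95% counting interval of 111.7 to 1594. Among the largest falls, Serpina12, the adipokine vaspin, was at 80.0 ± 26.4 CPM in CTRL and 7.78 ± 1.87 CPM in OPA1_LKO. Wfdc2 fell from 50.3 ± 22.9 to 5.72 ± 1.77 CPM and Tiam2, Clec2h and Dct had log2 fold changes of -3.06 ± 0.40, -2.98 ± 0.42 and -4.46 ± 0.63 (SE). Gpr12 and Slc39a5, a zinc transporter, stood at 2.64 ± 1.70 and 2.35 ± 1.75 CPM in CTRL and at 0.256 ± 0.112 and 0.341 ± 0.137 CPM in OPA1_LKO. The major urinary protein genes Mup15 and Mup17 had log2 fold changes of -3.34 ± 0.86 and -3.30 ± 0.63, with a wide spread in CTRL (449 ± 509 and 524 ± 429 CPM) and reads shared with their close relatives.

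**Figure D1:**
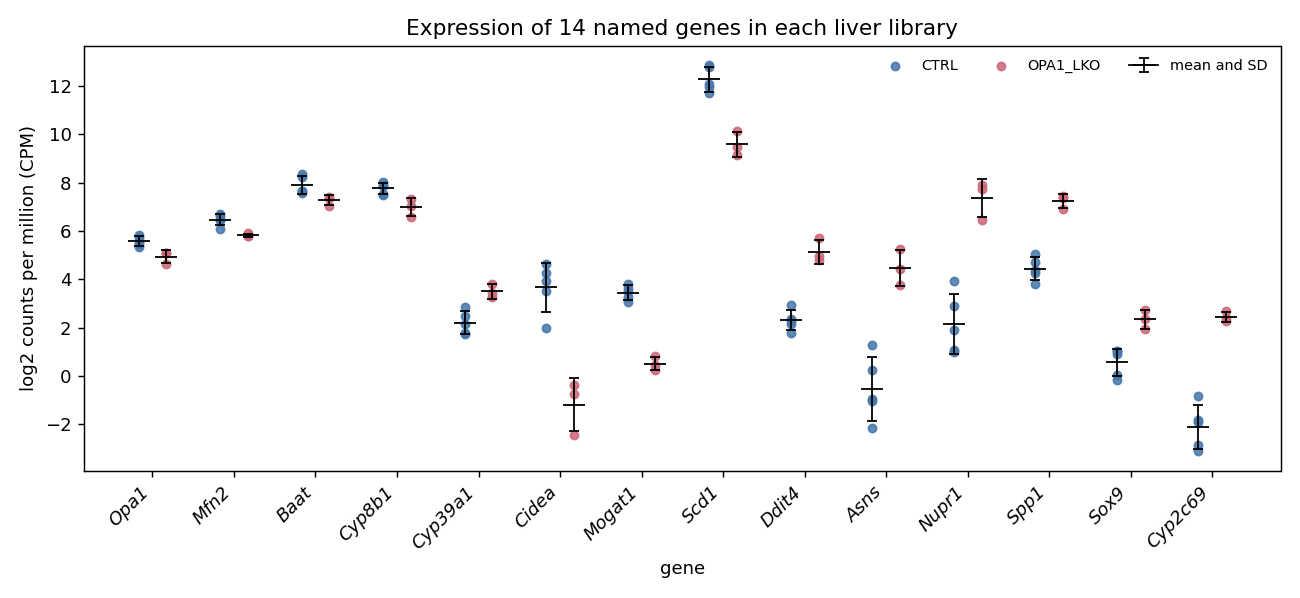
Level of 14 named genes in each library, as log2 CPM, with CTRL libraries in blue, OPA1_LKO libraries in red, and the mean and SD of each group in black. Asns and Nupr1 stand several log2 units higher and Cidea and Scd1 lower in OPA1_LKO, while Opa1 differs by 0.63 and Baat by 0.66 on the log2 scale, neither past the test threshold.

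The list of targets of ATF4, the transcription factor of the integrated stress response, held 24 tested genes, of which 10 rose and 0 fell (11 rose and 1 fell when adjusted over the list alone). Nupr1, a stress-induced chromatin protein, rose from 6.08 ± 5.52 to 179.8 ± 81.1 CPM. Trib3, the pseudokinase that feeds back on ATF4, rose from 14.3 ± 6.02 to 102.9 ± 53.3 CPM, and Ddit4, an inhibitor of mTORC1, from 5.11 ± 1.59 to 36.9 ± 13.4 CPM. Fgf21, a hormone released by the stressed liver and chosen after its values were seen, rose from 9.87 ± 5.93 to 70.8 ± 40.3 CPM. As a set the list stood above other genes (camera, adjusted p = 2.99e-09) with a median log2 fold change of 0.98, and its adjusted p was 0.487 with an estimated correlation. Without CTRL replicate 1, 14 members rose, and 6 did without OPA1_LKO replicate 1. Lonp1, the mitochondrial matrix protease, rose from 101.6 ± 6.17 to 219.3 ± 69.0 CPM and was the one changed gene of 13 mitochondrial chaperones and proteases, a list that was not called (camera, adjusted p = 0.223). None of 16 endoplasmic reticulum stress genes passed the edgeR test, and that list was not called either (camera, adjusted p = 0.766). The chaperone list was called higher with 1 surrogate variable (0.0284) and with log2(TPM + 1) and no filter (0.0335). The endoplasmic reticulum list was called higher with the replicate block (0.0498). With an estimated correlation these adjusted p were 0.587, 0.765 and 0.765.

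Of 21 genes for lipid uptake, droplets and lipolysis, 5 fell and 2 rose (9 and 3 when adjusted over the list alone). The counts were 7 and 4 without CTRL replicate 1 and 4 and 1 without CTRL replicate 3. Fitm1, which partitions triglyceride into droplets, fell from 120.7 ± 14.9 to 30.2 ± 2.77 CPM, and the droplet coat gene Plin4 from 98.6 ± 22.8 to 28.5 ± 6.90 CPM. Plin5, the droplet coat that tethers mitochondria, rose from 42.5 ± 6.53 to 78.8 ± 4.72 CPM, with CTRL replicate 3 below the other CTRL libraries at 31.2 CPM. The list was called lower (camera, adjusted p = 0.0154), with an adjusted p of 0.460 with an estimated correlation, and its camera p was 0.0727 without CTRL replicates 1 and 3. Of 21 genes for fatty acid and triglyceride synthesis, 2 fell and 1 rose (2 and 2 when adjusted over the list alone), and the list was not called (camera, adjusted p = 0.0645). Its camera p was 0.0186 without CTRL replicate 1, 0.0269 without CTRL replicate 2, 0.0397 without OPA1_LKO replicate 2 and 0.176 without CTRL replicate 3. It was also called lower by camera with upper-quartile factors (0.049), no low-count filter (0.0233) and limma-voom (0.0359). In the fits that called it, the adjusted p was between 0.585 and 0.773 with an estimated correlation. The members that changed were Scd1 and Mogat1, an acyltransferase raised in fatty liver that fell from 11.1 ± 2.24 to 1.44 ± 0.289 CPM, and Lpin1, a phosphatidate phosphatase and coactivator, which rose from 20.3 ± 7.04 to 93.9 ± 21.3 CPM. Of 22 lipoprotein genes 1 rose, Angptl4, an inhibitor of lipoprotein lipase, by 0.98 ± 0.24, while the list as a whole was called lower (camera, adjusted p = 0.0487), with an adjusted p of 0.742 with an estimated correlation. When adjusted over the list alone 1 lipoprotein gene rose and 5 fell. Over all genes 1 and 2 did so without CTRL replicate 1 and none without CTRL replicate 3. Without any one of CTRL replicates 3, 4 and 5 or OPA1_LKO replicates 2 and 3 that camera p was between 0.0588 and 0.124. In cholesterol synthesis 1 of 22 genes fell, Acat2, by 0.91 ± 0.18, and the list was not called (camera, adjusted p = 0.659). Here 2 fell without CTRL replicate 1, and 1 rose and 1 fell without CTRL replicate 3.

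Of 14 bile acid synthesis genes 1 fell and 1 rose (6 and 1 when adjusted over the list alone). Cyp46a1, a cholesterol 24-hydroxylase, was at 24.6 ± 12.4 CPM in CTRL and 5.03 ± 1.16 CPM in OPA1_LKO, and Cyp39a1, an oxysterol 7-alpha-hydroxylase, at 4.79 ± 1.64 and 11.5 ± 2.42 CPM. Cyp8b1, the 12-alpha-hydroxylase that sets the share of cholic acid, was at 220.3 ± 36.0 and 129.2 ± 32.5 CPM (adjusted p = 0.0535, edgeR with Benjamini-Hochberg) and Hsd3b7 at 391 ± 99.92 and 227.9 ± 3.74 CPM, neither past the threshold over all genes. Both passed when adjusted over the list alone. Cyp7a1, the rate-limiting enzyme of the classic pathway, was at 81.7 ± 23.1 and 124.5 ± 30.8 CPM and did not pass with either adjustment. The list was not called (camera, adjusted p = 0.0663), but it was called lower without CTRL replicate 1 (0.0346) and without CTRL replicate 3 (0.0273), and 3, 2 and 8 members fell without the first, without the second and without both of these libraries. With an estimated correlation its adjusted p was 0.742 over all libraries, 0.559 without CTRL replicate 1 and 0.842 without CTRL replicate 3, and its camera p reached 0.168 without CTRL replicate 4.

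Of 12 tested genes of the bile acid conjugation list 3 rose and 0 fell (4 and 3 when adjusted over the list alone), and these 3 were the sulfotransferase genes Sult2a1, Sult2a2 and Sult2a5, which encode enzymes that add sulfate to hydroxysteroids and bile acids and which share reads. Their relatives Sult2a7 and Sult2a8 differed by -2.09 ± 0.55 and -1.12 ± 0.44 (adjusted p = 0.0527 and 0.159, edgeR with Benjamini-Hochberg). Neither was past the threshold over all genes, though both passed when adjusted over the list alone (0.0101 and 0.0493). Sult2a5 had no count in CTRL and 194 counts over the OPA1_LKO libraries, at least 92.1-fold higher against a floor of 3 counts over the CTRL group. Sult2a1 had 1 count in CTRL and 168 in OPA1_LKO, a ratio of 239 with a 95% counting interval of 42.4 to 9503, and Sult2a2 had 2 and 174 counts, a ratio of 123.9 (33.8 to 1031). These large ratios belong to low levels. In OPA1_LKO, Sult2a1, Sult2a2 and Sult2a5 stood at 3.11 ± 3.57, 3.12 ± 2.65 and 3.40 ± 2.18 CPM. Sult2a8 was far more abundant, at 714.5 ± 384.7 CPM in CTRL and 329.4 ± 129.7 CPM in OPA1_LKO. Sult2a7 was at 5.07 ± 2.73 and 1.18 ± 0.728 CPM. Sult2a1 also belongs to the list of female-biased liver genes, so its rise is counted in both lists. The enzymes that join bile acids to taurine or glycine did not pass the test over all genes. Baat, the acyltransferase of that step, was at 245.8 ± 67.4 CPM in CTRL and 155.5 ± 21.0 CPM in OPA1_LKO, a log2 fold change of -0.66 ± 0.23 (adjusted p = 0.115, edgeR with Benjamini-Hochberg). When adjusted over the list alone, Baat did pass as lower. Slc27a5, the ligase before it, differed by -0.21 ± 0.28, and Csad, of taurine synthesis, was at 66.7 ± 22.1 and 133.5 ± 49.2 CPM, both short of the threshold over all genes. Csad passed as higher when adjusted over the list alone. Slc27a5 stood at 0.01 on the log2(TPM + 1) scale and at 0.00 without CTRL replicate 4. The mean log2 fold change of the list was 1.57, or 1.43 with the 3 sulfotransferases at their bound or ratio, and its median was -0.24 either way, so that mean and median differed in sign. Without CTRL replicate 4 the median was -0.11. The list was not called (camera, adjusted p = 0.635). In it 4 members rose and 1 fell without CTRL replicate 1. Of 15 bile acid and sterol transporters 1 fell and 0 rose (3 and 1 when adjusted over the list alone), and the list was not called (camera, adjusted p = 0.143). Without CTRL replicate 1, 3 fell and 1 rose, and none changed without CTRL replicate 3. Abcc3, an export pump of the sinusoidal membrane, fell from 195 ± 45.7 to 105 ± 16.6 CPM. Abcc3 passed in only 1 of the 8 fits that left out a library, with a highest adjusted p of 0.179 (edgeR with Benjamini-Hochberg). The uptake carriers Slc10a1 and Slco1b2 differed by -0.95 ± 0.29 and -1.32 ± 0.40, the export pump Abcb11 by -0.18 ± 0.13 and Abcc4 by 2.31 ± 0.63, with CTRL replicate 1 at 8.87 CPM and the other CTRL libraries between 1.03 and 1.79 CPM, and none of these 4 passed the test. No member of 9 bile acid receptor genes changed, or 1, which fell, without CTRL replicate 1, and that list was not called (camera, adjusted p = 0.158).

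Of 24 other genes of mitochondrial fusion, fission and cristae 1 fell, Mfn2, an outer membrane fusion protein, from 89.4 ± 13.7 to 56.7 ± 2.72 CPM, as it did when adjusted over the list alone. Mfn2 passed in only 1 of the 8 fits that left out a library, with a highest adjusted p of 0.167 (edgeR with Benjamini-Hochberg). In this list 3 fell without CTRL replicate 1 and 0 without CTRL replicate 3. Oma1, the protease that cuts OPA1 under stress, differed by -0.68 ± 0.19, Mief2 by -0.50 ± 0.15 and Immt, of the cristae junction, by -0.38 ± 0.14, none of them past the threshold. The list was called lower (camera, adjusted p = 0.0246) with a median of -0.22, and its adjusted p was 0.742 with an estimated correlation. That camera p was 0.109 without CTRL replicate 4, 0.0588 without OPA1_LKO replicate 3, 0.146 with log2(TPM + 1), where the median was -0.04, 0.394 with 1 surrogate variable and 0.204 with a block for the replicate number. The median was -0.0853 without CTRL replicate 4 and -0.14 without OPA1_LKO replicate 3. None of 50 nuclear subunits of the respiratory chain and ATP synthase passed the edgeR test, or 2, both lower, without CTRL replicate 1. Still, 42 had a negative fold change and the list was called lower (camera, adjusted p = 0.0246). Its adjusted p was 0.742 with an estimated correlation. Its median of -0.12 became 0.05 on the log2(TPM + 1) scale, which moved the median of all genes by 0.166. Its camera p was 0.386 on that scale, 0.319 with 1 surrogate variable, 0.0595 with upper-quartile scaling, 0.0835 without CTRL replicate 3, 0.172 without CTRL replicate 4 and 0.0605 without OPA1_LKO replicate 2. None of the 13 mitochondrially encoded proteins passed the test and all 13 had negative fold changes, with a median of -0.32, and the list was not called (camera, adjusted p = 0.127). Its camera p was 0.0186 without CTRL replicate 1, 0.00132 without OPA1_LKO replicate 3 and as high as 0.698 without OPA1_LKO replicate 2, and in the first pair of these fits the adjusted p was 0.693 and 0.785 with an estimated correlation. The median of the list was -0.0989 without CTRL replicate 3, -0.135 without OPA1_LKO replicate 2 and -0.645 without OPA1_LKO replicate 3. Of 19 genes of mitochondrial fatty acid oxidation 1 fell, Hadh, by 0.73 ± 0.17, and 0 fell without CTRL replicate 3. That list was called lower (camera, adjusted p = 0.0421), with an adjusted p of 0.742 with an estimated correlation, and its camera p was between 0.0648 and 0.185 without any one of CTRL replicates 2, 4 and 5 or OPA1_LKO replicate 3, and 0.113 with log2(TPM + 1), 0.496 with 1 surrogate variable and 0.199 with the block. In the tricarboxylic acid cycle 2 of 20 genes fell, Pdha1 by 0.70 ± 0.15 and Suclg2 by 0.53 ± 0.13, and the list was not called (camera, adjusted p = 0.223). The count that fell was 5 without CTRL replicate 1 and 0 without CTRL replicate 3. Its median of -0.08 became 0.10 on the log2(TPM + 1) scale.

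**Figure D2:**
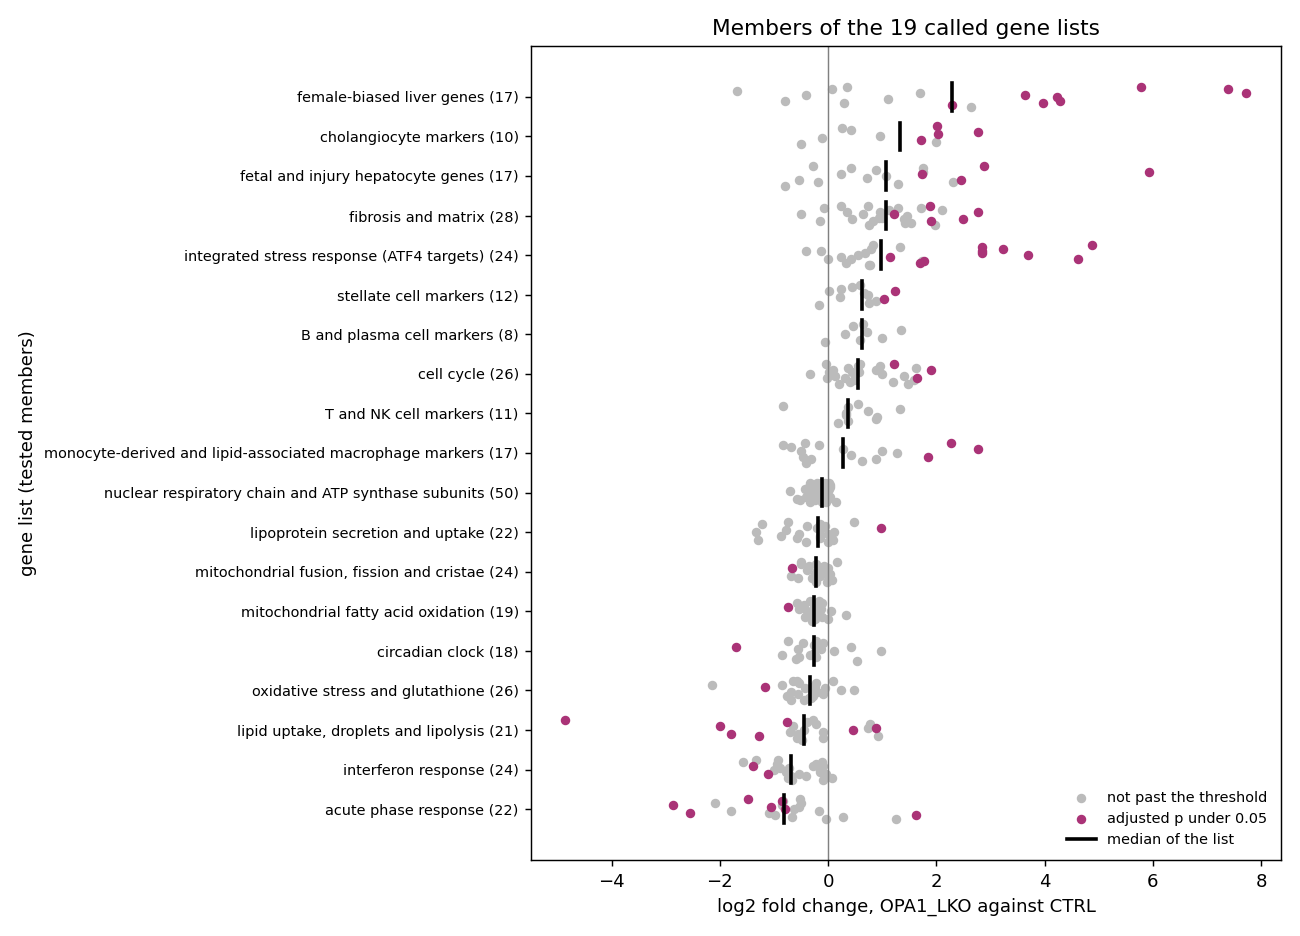
Log2 fold change of each tested member of the 19 called gene lists, OPA1_LKO against CTRL, with the number of tested members in parentheses, members with an adjusted p under 0.05 in purple, the others in grey, and the list median as a black bar. Medians run from -0.82 for the acute phase response to 2.30 for female-biased liver genes, and the changed members of the mitochondrial lists are few.

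Genes that female mouse liver expresses above male liver rose in 8 of 17 tested cases and fell in 0 (11 and 1 when adjusted over the list alone). Cyp3a41a rose from 0.0868 ± 0.110 to 21.0 ± 11.1 CPM, Cyp2c69 from 0.272 ± 0.178 to 5.50 ± 0.795 CPM and the estrogen sulfotransferase Sult1e1 from 0.443 ± 0.236 to 5.59 ± 2.07 CPM. Cyp3a44 had 2 counts in CTRL and 101 in OPA1_LKO, a ratio of 71.9 with a 95% counting interval of 19.4 to 601.8, and it shares reads with Cyp3a41a. The median of the list was 2.30, the same with its low genes at their ratio, and it was called higher (camera, adjusted p = 2.05e-07), with an adjusted p of 0.334 with an estimated correlation. Of 19 male-biased genes 2 rose and 1 fell (2 and 4 when adjusted over the list alone), and the list was not called (camera, adjusted p = 0.289). The counts were 3 and 4 without CTRL replicate 1. Egfr, the epidermal growth factor receptor, rose from 60.9 ± 10.8 to 174.4 ± 53.3 CPM, Serpina1e from 322.9 ± 268 to 1886 ± 19 CPM, and the complement gene C8a fell by 0.78 ± 0.19. Mup7 was at 2088 ± 2304 CPM in CTRL and 124.8 ± 39.3 CPM in OPA1_LKO, with all 3 OPA1_LKO libraries below all CTRL libraries and an adjusted p of 0.0564 (edgeR with Benjamini-Hochberg), short of the threshold. That p was 0.0199 without CTRL replicate 1 and 0.0373 without CTRL replicate 3.

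Of 22 acute phase genes 6 fell and 1 rose (12 and 2 when adjusted over the list alone). The count that fell was 10 without CTRL replicate 1, 4 without CTRL replicate 3, 0 without OPA1_LKO replicate 1 and 1 without OPA1_LKO replicate 3. The serum amyloid genes Saa1 and Saa2 fell from 157.8 ± 67.3 to 27.0 ± 14.5 CPM and from 84.9 ± 38.9 to 11.6 ± 6.13 CPM, the orosomucoid genes Orm1 and Orm3 fell by 1.05 ± 0.21 and 1.48 ± 0.29, and Apcs, which encodes serum amyloid P, rose from 194.4 ± 55.6 to 602 ± 308.5 CPM, with CTRL replicate 1 below the other CTRL libraries at 102.9 CPM. The list was called lower (camera, adjusted p = 0.000117), with an adjusted p of 0.566 with an estimated correlation. In the interferon response 2 of 24 genes fell and 0 rose (6 and 0 when adjusted over the list alone), Ifit1 by 1.38 ± 0.26 and Oasl1 by 1.11 ± 0.22, while 0 fell without OPA1_LKO replicate 1 or 3. That list was called lower (camera, adjusted p = 0.0021), with an adjusted p of 0.742 with an estimated correlation and an adjusted p of 0.0834 in camera without CTRL replicate 1. Of 26 oxidative stress and glutathione genes 1 fell, Gclc, of glutathione synthesis, from 194.3 ± 28.9 to 87.0 ± 8.31 CPM, also when adjusted over the list alone. Here 2 fell and 1 rose without CTRL replicate 1. The list was called lower (camera, adjusted p = 0.00522, and 0.0526 without CTRL replicate 1), with an adjusted p of 0.666 with an estimated correlation. None of 18 inflammatory signalling genes changed, and the list was not called (camera, adjusted p = 0.941). Its median was -0.18, but 0.30 without CTRL replicate 1, where 2 members rose. With 1 surrogate variable it was called lower (0.00973), with an adjusted p of 0.730 with an estimated correlation.

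Matrix and fibrosis genes rose in 5 of 28 tested cases and fell in 0 (10 and 0 when adjusted over the list alone), and in 12 without CTRL replicate 1. Spp1, or osteopontin, rose from 22.7 ± 7.36 to 154 ± 28.5 CPM, Ctgf from 5.71 ± 2.52 to 32.0 ± 18.04 CPM, Tgfb3 by 1.88 ± 0.40 and the basement membrane collagen Col4a2 by 1.21 ± 0.26. The list was called higher (camera, adjusted p = 2.05e-07), with an adjusted p of 0.735 with an estimated correlation. Of 10 cholangiocyte markers 4 rose and 0 fell (5 and 0 when adjusted over the list alone), namely Spp1, the duct transcription factor Sox9 (1.56 ± 0.554 to 5.18 ± 1.35 CPM), Muc1 and Krt7, by 2.02 ± 0.39 and 2.04 ± 0.40. The list was called higher (camera, adjusted p = 2.61e-05), with an adjusted p of 0.460 with an estimated correlation. CTRL replicate 3 stood apart for the duct keratin Krt19, chosen with Epcam after the values were seen, at 22.3 CPM against 0.319 to 1.03 CPM in the other CTRL libraries and 2.13 to 5.67 CPM in OPA1_LKO, and 8 cholangiocyte markers rose without that library. The count was 2, 2 and 1 without OPA1_LKO replicates 1, 2 and 3. Of 12 stellate cell markers 2 rose and 0 fell (6 and 0 when adjusted over the list alone), among them Hand2 from 8.33 ± 1.51 to 19.7 ± 4.48 CPM, and 1 rose without CTRL replicate 3. That list was called higher (camera, adjusted p = 0.00167, and 0.0632 without OPA1_LKO replicate 2), with an adjusted p of 0.666 with an estimated correlation. Of 17 fetal and injury genes 4 rose and 0 fell (8 and 0 when adjusted over the list alone), H19, Cd24a by 2.45 ± 0.37, the fetal growth factor Igf2 by 2.88 ± 0.63 and Krt23 by 1.73 ± 0.41, and the list was called higher (camera, adjusted p = 0.000207), with an adjusted p of 0.460 with an estimated correlation. Among these 7 rose without CTRL replicate 1. Of 26 cell cycle genes 3 rose and 0 fell (6 and 0 when adjusted over the list alone), Ccnd1, or cyclin D1, from 13.3 ± 5.36 to 49.9 ± 25.5 CPM, Plk1 by 1.64 ± 0.39 and Cdk1 by 1.22 ± 0.31. The count that rose was 5 without CTRL replicate 1 and 0 without OPA1_LKO replicate 1. That list was called higher (camera, adjusted p = 0.000117), with an adjusted p of 0.666 with an estimated correlation.

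Of 17 markers of monocyte-derived and lipid-associated macrophages 3 rose, Spp1, Fabp5 by 1.85 ± 0.35 and Cd63 by 2.28 ± 0.58, and 7 rose without CTRL replicate 1. This macrophage list was called higher (camera, adjusted p = 0.0246) with an adjusted p of 0.742 with an estimated correlation. None of 11 T and NK cell markers and none of 8 B and plasma cell markers passed the edgeR test, while both lists were called higher (camera, adjusted p = 0.0446 and 0.0386), with adjusted p = 0.742 and 0.666 with an estimated correlation. These 3 calls were each lost without CTRL replicate 4, with camera p of 0.109, 0.0948 and 0.0756. The macrophage call was also lost without CTRL replicate 2 (0.0561) or OPA1_LKO replicate 2 (0.0685), the T and NK call without CTRL replicate 2 (0.0940), OPA1_LKO replicate 2 (0.0604) or OPA1_LKO replicate 3 (0.0834), and the B and plasma cell call without CTRL replicate 5 (0.0648) or OPA1_LKO replicate 3 (0.143). None of 14 Kupffer cell markers or 13 endothelial markers changed, and neither list was called (camera, adjusted p = 0.191 and 0.223). The Kupffer list was called lower with 1 surrogate variable (0.00678) and with the block for the replicate number (0.00253), and the endothelial list was called higher without OPA1_LKO replicate 3 (0.0136), with adjusted p of 0.750, 0.765 and 0.785 with an estimated correlation. Of 16 hepatocyte markers 2 rose, Tat and Ahsg, and that list was not called (camera, adjusted p = 0.792). Erythroid markers did not change in 5 tested genes (camera, adjusted p = 0.274), though 1 fell without CTRL replicate 1, and adipocyte and pancreatic acinar markers had 4 and 1 tested genes, too few for the list test.

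Across the 46 lists, 19 were called with the preset correlation, 10 higher and 9 lower, 0 were called with an estimated correlation, and 6 were called by fry. The count of changed genes depended on single libraries. It was 198 without OPA1_LKO replicate 1, 231 without OPA1_LKO replicate 3, 422 without CTRL replicate 5, 448 without CTRL replicate 2 and 502 without CTRL replicate 4. With upper-quartile scaling 547 genes were higher and 270 lower. Of 96 counts of higher or lower list members, 32 moved by more than 1.5-fold without CTRL replicate 1, 31 without OPA1_LKO replicate 1, 29 without OPA1_LKO replicate 3 and 12 to 23 without any one of the others. Among 90 named genes that changed, 41 passed in all 8 fits that left out a library, among them Asns, Nupr1, Trib3, Ddit4, Lonp1, Lpin1, Scd1, Cidea, Fitm1, Spp1, Cyp3a41a, Sult2a1, Sult2a2 and Sult2a5, while 46 did not pass without OPA1_LKO replicate 1 and 43 did not pass without OPA1_LKO replicate 3. Mfn2, Abcc3, Hadh, Suclg2, Cdk1 and Cd63 each passed in only 1 of the 8 fits. Of the 846 changed genes, 831 had all 3 OPA1_LKO libraries outside the range of the CTRL libraries, as had 16.4% of all tested genes, against 3.57% by chance.

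**Figure D3:**
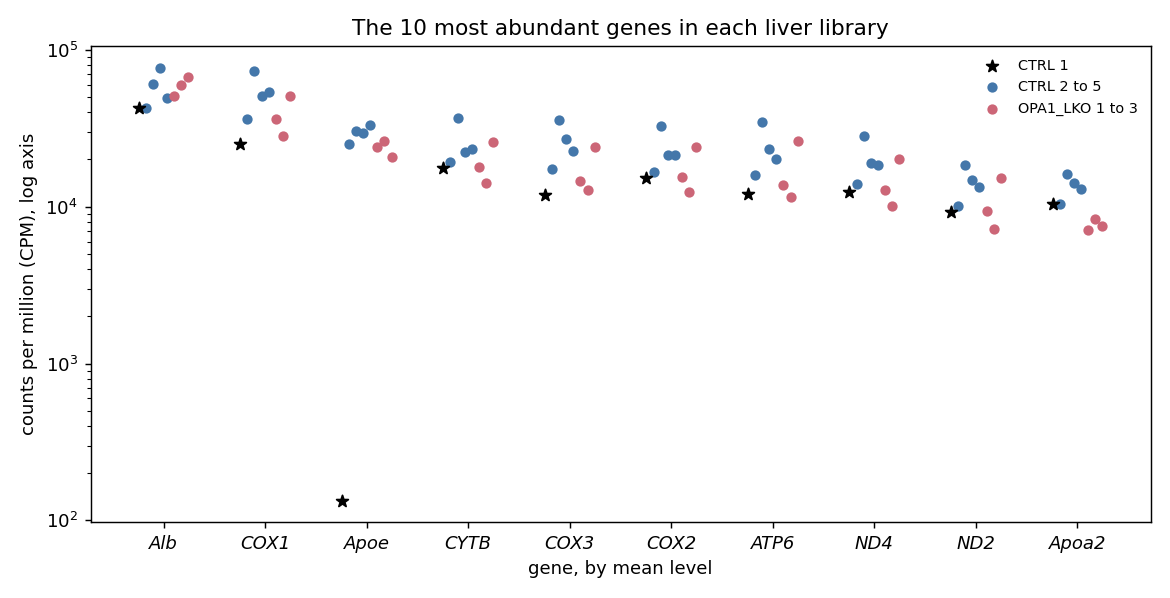
Level of the 10 most abundant genes in each library in CPM, on a log axis, with CTRL replicate 1 as black stars, the other CTRL libraries in blue and the OPA1_LKO libraries in red. Apoe in CTRL replicate 1 lies at 134 CPM, against 20760 to 33180 CPM in the other 7 libraries.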

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

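Of the tests in this part, those for a poor library, female RNA, male-pattern growth hormone signalling, a lower share of hepatocytes and more duct tissue were chosen only after the result was seen. A CTRL library is singled out here where its gap to the nearest of the other CTRL libraries, on the log2 CPM scale for genes, takes an unusually large share of the range of the 5 CTRL libraries. Of 125 sets of values examined, for genes and for measures such as library totals, 12 were singled out, all of them genes. Chance gives about 1 in 20, or 6.25, but Xist, Krt19, Epcam and Apcs among the 12 were chosen after their values were seen, which inflates the 12. Of these 12, 7 were singled out by CTRL replicate 1 and 3 by CTRL replicate 3.

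Apoe in CTRL replicate 1 was at 133.8 CPM against 25200 to 33180 CPM in the other CTRL libraries, a gap of 0.95 of the range. The median hepatocyte marker differed by -0.438 on the log2 scale from the other 7 libraries, which argues against a loss of hepatocyte RNA as large as the fall in Apoe. Lesser faults of this library were not tested, and its quality weight in limma-voom was the lowest of all libraries, at 0.483. Among genes of at least 100 CPM, 0 others were 8-fold or more lower in this library and its neighbours Apoc1 and Apoc4 differed by -0.12 and -0.52, so that a difference at the Apoe gene itself in this sample may be the source. A stretch of another strain around Apoe cannot be told apart from it, because 0.557 strongly differing genes were expected within 10 Mb and 1 was found (Fisher's exact p = 0.43).

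In the female-biased list 8 of 17 genes rose in OPA1_LKO, with a median log2 fold change of 2.30 and an adjusted p of 0.334 with an estimated correlation. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty differed by a median of -0.233 and Xist was at most 0.185 CPM in OPA1_LKO, which argues against female animals or female RNA in that group. A general rise of lowly expressed genes is argued against by the position of the list at percentile 100 of 10000 lists matched on mean expression, the highest of which had a median of 0.56. Lower male-pattern growth hormone signalling in the knockout is a hypothesis that cannot be told apart from other causes, since the male-biased list was not called (camera, adjusted p = 0.289). The deletion of Opa1 stays open as a cause.

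In OPA1_LKO 4 of 10 cholangiocyte, 2 of 12 stellate and 5 of 28 matrix genes rose, with adjusted p of 0.460, 0.666 and 0.735 for these lists with an estimated correlation. CTRL replicate 3 carried the highest level of the duct keratin Krt19. Another duct keratin, Krt7, was at 1.17 CPM in that library and at 2.86 to 4.41 CPM in OPA1_LKO. Over all 8 libraries Krt19, Epcam, Cldn7 and Cftr had log2 fold changes of -0.50, 0.96, 0.43 and -0.11, with a median of 0.161 and none past the threshold. Without CTRL replicate 3 they had 2.42, 3.48, 4.52 and 3.60, all 4 past it (adjusted p of 0.0258, 0.00187, 0.00565 and 0.0316 by edgeR with Benjamini-Hochberg), but that library stood apart in these same genes, so that this decides nothing. The cholangiocyte and stellate score minus the Kupffer and endothelial score was 1.2 higher in OPA1_LKO (exact permutation p = 0.107), at 0.59 to 1.01 there, 0.738 in CTRL replicate 3 and -1.21 to -0.324 in the other CTRL libraries. The cholangiocyte and stellate score alone was 1.18 higher in OPA1_LKO, and the Kupffer and endothelial score differed by -0.0234. Within the latter, Kupffer markers had a median log2 fold change of -0.41 and endothelial markers of 0.30. More duct tissue in the OPA1_LKO samples and a lower share of hepatocyte RNA cannot be told apart, because CTRL replicate 3 lay within the OPA1_LKO range of the score and above it for all 4 duct genes.

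The other genes are given as values. Krt19 and Epcam in CTRL replicate 3 were at 22.3 and 16.8 CPM, with gaps of 0.753 and 0.853 of the range, and Plin5 there was at 31.2 CPM, with a gap of 0.777. In CTRL replicate 1, Xist was at 8.13 CPM with a gap of 0.836, beside Ddx3y at 7.91 CPM and Eif2s3y at 35.9 CPM, and whether RNA of another sample was mixed into this library stays open. Also there, Tenm2 was at 1.43 CPM with 0.843, Wfdc3 at 0.372 CPM with 0.715, and Abcc4 at 8.87 CPM with 0.752. Apcs and Acat2 in the same library were at 102.9 and 23.9 CPM, with gaps of 0.725 and 0.717. In CTRL replicate 2, Orm1 was at 484.3 CPM with a gap of 0.766, and Sult2a1 had the one count of the CTRL group, with a gap of 1, the whole range.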

How the results depend on the processing

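Fits without CTRL replicates 1 and 3 together were chosen only after the data were seen, and all other alternatives in this part were chosen before the data were examined. Against 846 changed genes (469 higher, 377 lower), DESeq2 gave 1596 (786 and 810), limma-voom with quality weights 2749 (1385 and 1364), log2(TPM + 1) 333 (259 and 74), log2(TPM + 0.1) 318 (240 and 78), log2(TPM + 1) with no filter 418 (359 and 59), and the test against a fold of 1.5 gave 199. With no filter on low counts 238 genes were lower, and without CTRL replicates 1 and 3 together 2919 changed (1491 and 1428). DESeq2 shared 845 and limma-voom 839 of the 846 genes, and no setting gave a shared gene the opposite direction. With the replicate block, whose group effect rests on replicates 1 to 3 of each group, 367 genes changed (193 and 174). Its difference from the main fit therefore cannot be told apart from the loss of CTRL replicates 4 and 5. After the mean of each gene in its group was subtracted from log2 CPM, same-numbered libraries had correlations of 0.072, 0.0537 and 0.175. OPA1_LKO replicates 1 and 3 correlated best with the CTRL library of the same number, and OPA1_LKO replicate 2 with CTRL replicate 5 (0.174). As all of these were low, the numbers were not taken as pairs, but pairing is not excluded. Leaving out 1 library gave 198 (without OPA1_LKO replicate 1) to 1701 (without CTRL replicate 1) changed genes, 144 to 924 higher and 54 to 777 lower, and 12 (without CTRL replicate 4) to 21 lists called. The count of lists was 0 with an estimated correlation and 6 with fry. For Opa1 the log2 fold change was -0.63 with DESeq2, -0.77 with limma-voom and -0.74 without CTRL replicates 1 and 3 together, each past the threshold, and -0.71 to -0.49 with 1 library left out. Its transcript NM_133752.3 differed by -5.939 in counts scaled by library totals alone, without TMM factors (exact permutation p = 0.0357). That p is the smallest the test can give. It was not adjusted over the transcript comparisons, so this difference is not taken as a change. The Opa1 transcript XM_006522655.2 differed by -0.111 to 0.109 TPM with 1 library left out. Slc27a5, at -0.21, was at 0.0149 with log2(TPM + 1), with and without the filter, 0.0151 with log2(TPM + 0.1), 0.205 with 1 surrogate variable, 0.132 with the replicate block, and -0.352 to 0.00117 with 1 library left out. Krt19, at -0.50, was at 1.26 with limma-voom, 0.723 with log2(TPM + 1), with and without the filter, 1.25 with log2(TPM + 0.1), 1.04 with the replicate block and 2.16 without CTRL replicates 1 and 3 together, and lay between -1.03 (without OPA1_LKO replicate 2) and 2.42 (without CTRL replicate 3) with 1 library left out. Apoe, at 0.00, was at -0.303 without CTRL replicates 1 and 3, and between -0.318 (without CTRL replicate 1) and 0.153 with 1 library left out. Over all named genes and settings 1921 results kept direction and side of the threshold, 309 no longer passed, 60 newly passed and 17 turned direction. The cause was not tested, except that fits with fewer libraries have fewer degrees of freedom. With log2(TPM + 1), 1 surrogate variable and the replicate block, camera p was 0.0644, 0.173 and 0.229 for the lipoprotein list, 0.125, 0.218 and 0.0924 for the circadian list, 0.0514, 0.783 and 0.204 for the macrophage list and 0.0994, 0.0811 and 0.0615 for the B cell list, none of them called, and for the T cell list it was 0.319 and 0.0987 with the last pair. Of the 27 lists not called, 13 were called in at least 1 other setting, and the lowest adjusted p among those calls was 0.456 with an estimated correlation. At the depth, spread and number of these libraries the simulation recovered 38% of genes changed by 2-fold, and which of these limits it was not tested.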

Other observations

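Of the tests in this part, only the fit without CTRL replicates 1 and 3 together was chosen after the result was seen. Of 23 glycolysis and gluconeogenesis genes 4 rose and 1 fell (5 and 3 when adjusted over the list alone), and the list was not called (camera, adjusted p = 0.974), with 2 lower without CTRL replicate 1. Igfbp1, a binding protein induced in fasting, rose from 10.2 ± 6.82 to 99.8 ± 23.9 CPM, Pck1, of gluconeogenesis, from 1075 ± 214.6 to 2226 ± 488.6 CPM, and Pck2 rose by 1.54 ± 0.27. Of 24 genes of the urea cycle and amino acid breakdown 3 rose and 0 fell (7 and 0 when adjusted over the list alone), Tat from 461.7 ± 132.8 to 1405 ± 290.8 CPM, Got1 by 1.37 ± 0.30 and Asl by 1.03 ± 0.25, and that list was not called (camera, adjusted p = 0.127). The count that rose was 4 without CTRL replicate 1 and 2 without CTRL replicate 3. Its list was called higher without any one of CTRL replicates 2 and 4 and OPA1_LKO replicate 1 (0.0302 to 0.0347), with adjusted p of 0.764 to 0.806 with an estimated correlation. It was also called higher with 1 surrogate variable (7.37e-05), the replicate block (0.0213) and the log2 TPM scales (0.0247 to 0.0412). For those fits the adjusted p was 0.587 to 0.814 with an estimated correlation. Of 20 peroxisomal and omega oxidation genes, targets of PPAR alpha, 3 rose and 1 fell (3 and 5 when adjusted over the list alone), with Cyp4a31 at 11.1 ± 4.85 CPM in CTRL and 87.9 ± 32.3 CPM in OPA1_LKO, Acot2 and Pdk4, which holds back pyruvate oxidation, higher by 1.75 ± 0.35 and 1.39 ± 0.27, and Vnn1 at -1.49 ± 0.33, and the list was not called (camera, adjusted p = 0.622), with 4 lower without CTRL replicate 1. These adjusted p-values per gene came from edgeR with Benjamini-Hochberg adjustment.

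Of 18 periportal genes 3 fell and 1 rose (4 and 4 when adjusted over the list alone), with Cyp2f2 at 398.5 ± 52.1 CPM in CTRL and 214.6 ± 28.6 CPM in OPA1_LKO, and neither that list nor the pericentral list, in which 1 of 18 genes fell, was called (camera, adjusted p = 0.941 and 0.0786). Without CTRL replicate 1, 4 periportal genes fell and 2 rose, and without CTRL replicate 3 no pericentral gene fell. The pericentral list was called lower without CTRL replicate 3 (0.0395) and without OPA1_LKO replicate 2 (0.00601), with adjusted p of 0.842 and 0.687 with an estimated correlation. Of 18 circadian genes 1 fell (2 when adjusted over the list alone), Bhlhe41 by 1.69 ± 0.25. In it 4 fell without CTRL replicate 1. That list was called lower (camera, adjusted p = 0.0446), with an adjusted p of 0.735 with an estimated correlation, and its camera p was between 0.0561 and 0.105 without any one of CTRL replicates 2, 3 and 4 or OPA1_LKO replicates 1 and 2. Of 23 xenobiotic genes 2 fell and 1 rose, or 3 and 2 without CTRL replicate 1 (camera, adjusted p = 0.158), of 16 genes of mitochondrial DNA maintenance 1 rose (0.974), and of 14 nuclear-retained and immediate-early transcripts 1 rose, Egr1, by 1.99 ± 0.37 (0.0645). This last list, a sign of RNA handling, had 11 members with positive fold changes, 2 of them past the test without CTRL replicate 1, and was called higher without CTRL replicate 1 (0.0389), without CTRL replicate 3 (0.0298) and without both (0.00589), with adjusted p of 0.559, 0.765 and 0.571 with an estimated correlation. The xenobiotic list was called lower without OPA1_LKO replicate 2 (0.0314), with an adjusted p of 0.773 with an estimated correlation. None of 22 one-carbon, 16 p53 target and 6 ketogenesis genes changed, and these lists were not called (camera, adjusted p = 0.923, 0.223 and 0.133). Without CTRL replicate 1, 3 one-carbon genes rose and 1 fell, and 1 p53 target rose, as 1 did without OPA1_LKO replicate 2.

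A hypothesis was that genes near Opa1 differ because the altered allele may carry a stretch of another mouse strain. Within 10 Mb of Opa1 10 of 144 tested genes changed where 8.79 were expected (Fisher's exact p = 0.6). This argues against a large excess of changed genes in that window. An effect on few genes, or a shorter stretch, could not be told from the expected number and stays open. Over the 56 ways to divide the libraries into 5 and 3, 2 gave at least as many changed genes as the 846 of the real groups, the real one included, and the highest other gave 1062. Likewise 2 gave as many higher genes (469, highest other 634) and 2 as many lower genes (377, highest other 428), a share of 3.57% each. A split other than the real groups gave more on each of these counts, so this share does not exclude chance. The split with 1062 set CTRL replicates 2, 4 and 5 against the rest, which points to a structure among the libraries in which CTRL replicates 1 and 3 lie nearer to OPA1_LKO, and the other 54 splits gave 0 genes by edgeR. For the 19 gene lists called, 21 of the 56 splits gave as many and the highest other gave 26, so that chance cannot be excluded for the number of lists.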
